A study of Pimephales promelas with 28 samples.

How the data were processed

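Liver RNA of sexually regressed female fathead minnows (Pimephales promelas) was measured on 28 one-colour Agilent arrays, with Cy3 as the dye, per the labels. The labels place 4 control arrays at 24 h, 5 at 48 h and 5 at 72 h, and 5 phenanthrene arrays at 24 h, 5 at 48 h and 4 at 72 h. The labelled exposure was 29 ng per L for each phenanthrene array and 0 ng per L for each control; the unit is as the labels give it and no other source for it was used here. Replicate numbers were given in the order of deposit and only name an array, so no paired analysis was made. Whether each array held the RNA of a separate fish is not stated in the labels, and the p-values measure the spread between these arrays.

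Each deposited scanner table gives, per the file headers, the output of Agilent Feature Extraction 10.7.1.1 for 15744 spots, of which 536 are control spots and 15208 are probes with 1 spot each. Its processed signal is a linear fluorescence intensity after the background correction of that software, per the file headers. The authors also deposited a series-level table of log2 values, with 1 column per array and 1 further column of a baseline that belongs to no sample. The normalization of those log2 values is not given in the sources used here. Over all probes, 27 of its columns correlated at 0.994 or more with the log2 processed signal of their own array, and column medians lay between 4.96 and 6.98. The slopes of 0.928 to 1.27 set the log base and the direction, while the centring remained unknown. For exposed 24 h replicate 3 the correlation was 0.953 over all probes and 0.999 over the probes well above background, and that column correlated at 0.964 with exposed 24 h replicate 2. For exposed 24 h replicate 5 the authors' table held values for 10683 probes only.

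The identifiers in the files are expressed-sequence contigs for 11862 probes, gi numbers for 3309 and clone names for 37. None paired a probe with a gene name, and 0 of the 15208 identifiers matched the reference table of 64593 genes used here. The 33 gene lists chosen before the data were examined therefore matched 0 probes, and the planned tests of those lists (camera and fry) were not run. The planned rule for naming genes also needs gene names. In its place, a rule chosen after the identifiers had been seen named the 2 higher and the 2 lower probes with the smallest unadjusted p in each phenanthrene comparison. It named 1 of each for the control time comparisons and 1 probe for the difference between times. Probes that passed only under an alternative, UF_Ppr_AF_106942 and UF_Ppr_AF_109657, are named after their values were seen.

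The log2 processed signal of each array was reduced by the 75th percentile of its 15208 probes. Spots that the scanner software marked as non-uniform or as population outliers, 779 over all arrays, were left out, and saturated spots were kept. Probes were tested if they were well above background on at least 3 arrays of at least 1 group, which left 11492. The 6 group means were fitted in 1 model with limma 3.58.1 in R 4.3.3, with 22 residual degrees of freedom, and two-sided moderated tests were adjusted by Benjamini-Hochberg within each comparison at 0.05. The comparisons were phenanthrene against control at each time, the mean of the 3 differences, an F test of whether the effect differed between times, and the 3 comparisons of control times. Log2 differences of probes near background depend on the background correction. Where a probe was not well above background on any array of 1 group, the fold is a bound against the lowest signal well above background, written as at least N-fold. This bound compares means of the processed signal and does not carry over to another background correction.

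Unless another number of probes is given, principal components, correlations and counts of groups without overlap used the 10933 tested probes with no left-out spot. The counts of probes without overlap and the permutation tests of whole profiles were chosen after seeing the data. The number of arrays limits the precision: the within-group SD had a median of 0.80 log2 units over probes, and 31.0% of probes had an SD above 1. No pair of arrays correlated above 0.959 in the log2 processed signal of all 15208 probes. The 28 arrays lay on 5 slides of 4 to 7 arrays, scanned on 2 days, and each group spanned 3 slides. The slides scanned on the first day held 8 arrays, all of 48 h.

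The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 on the median spot signal (the mean spot signal was not used here), other filters on dim probes, slide as a fixed block (meant where slide is called a block) or a random one, fits to only the arrays compared, array weights, a trended and robust prior, the authors' deposited table, an adjusted p of 0.1, effects within slides, and each array left out in turn. Further alternatives were chosen after seeing the data: leaving out 3 arrays of doubtful quality together, keeping the marked spots, and scan day as a block. The fit was tested on simulated data in which whole-array residuals were permuted and 200 of 10933 probes were changed in each of 20 draws, 50 each by 2-, 4-, 8- and 16-fold. It made 18.8 false calls per draw, or 13.9% of its calls, for the control comparison of 48 h with 72 h, and between 1.51% and 3.96% of calls were false for the other comparisons.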

Results

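The series measured liver transcripts of sexually regressed female fathead minnows, a small freshwater fish used in toxicology, after 24, 48 or 72 h with or without phenanthrene, a polycyclic aromatic hydrocarbon with 3 fused rings. Its title states the purpose as following liver gene expression over 72 h of exposure. The 28 arrays fell into 6 groups of 4 or 5. The 75th percentile of signal ran from 134.5 to 1253 units over the arrays, with a median of 277. Between 5127 and 12278 of the 15208 probes were well above background, with a median of 10433. The probes carry contig or clone identifiers and no gene names, so transcripts are named below by probe.

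Signal quality was uneven among exposed arrays. The bright-corner control spots lay at 17.87 log2 units on exposed 48 h replicate 1 and 19.004 on exposed 72 h replicate 4, against 10.07 to 11.85 on the 14 control arrays. The same 2 arrays had 201 and 498 spots marked non-uniform, where no control array had more than 13. Exposed 24 h replicate 3 had the fewest probes well above background, 5127, and the highest negative-control signal, 4.23 log2 units against a median of 1.03 over all arrays. These 3 arrays are called the arrays of doubtful quality.

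**Figure D1:**
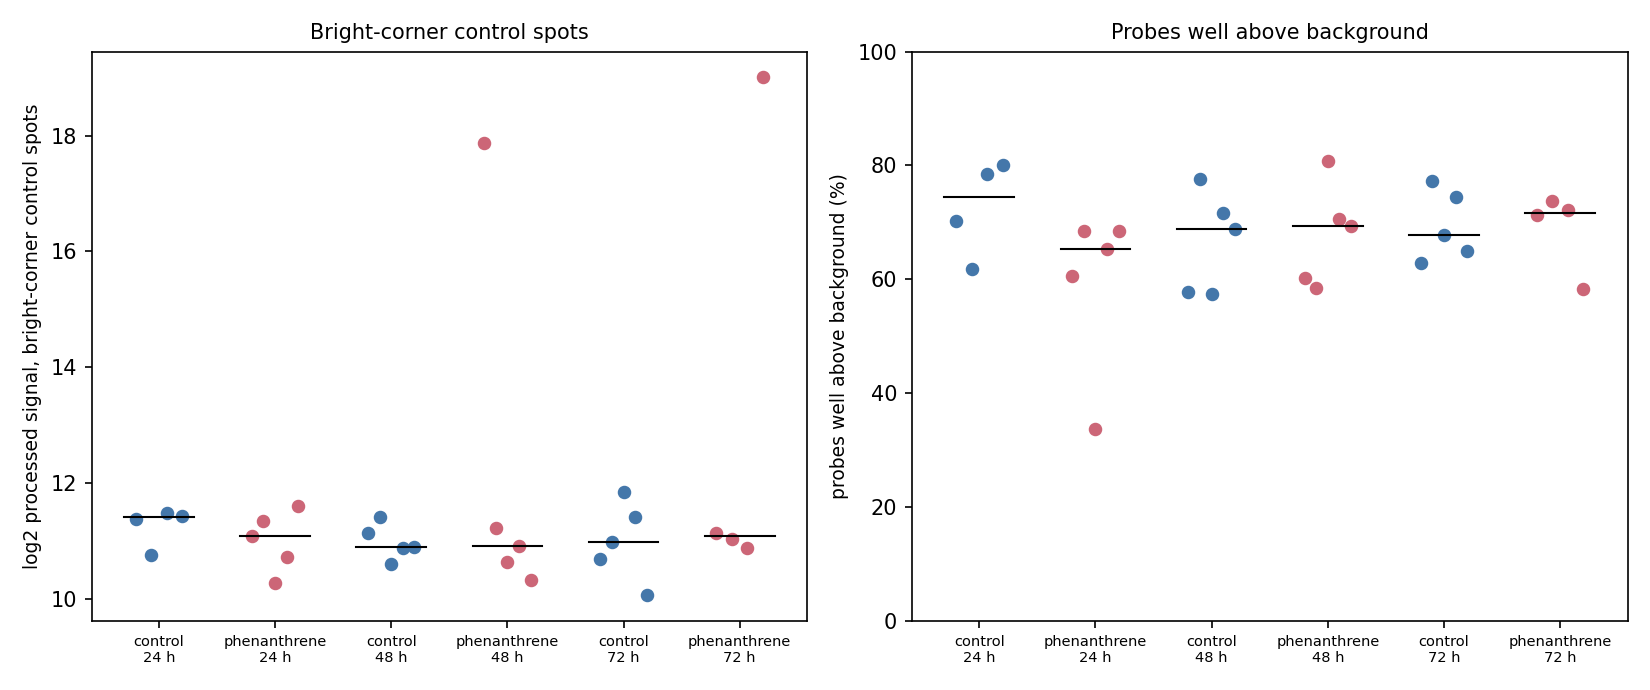
Each point is 1 array, grouped by agent and time, and the line marks the group median; the left panel gives the log2 processed signal of the bright-corner control spots and the right panel the percentage of probes well above background. Exposed 48 h replicate 1 and exposed 72 h replicate 4 stand at 17.87 and 19.004 in the left panel, and exposed 24 h replicate 3 stands at 33.7% in the right panel.

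At 24 h, no probe separated exposed from control liver at the threshold. The probe with the smallest p among those higher in exposed liver was UF_Ppr_AF_102490, at -3.09 ± 1.08 (SD, n = 5) against -5.68 ± 1.93 (SD, n = 4) log2 units relative to the 75th percentile, a difference of 2.59 with an SE of 0.66, and well above background on 3 of 5 exposed and 1 of 4 control arrays. UF_Ppr_AF_105225 was well above background on 3 of the 5 exposed arrays and on 0 of the 4 controls, at least 2.76-fold higher by the processed signal. With normexp background correction, which draws dim spots together, the difference was 0.42 log2 units for UF_Ppr_AF_102490. It was 0.56 for UF_Ppr_AF_105225, short of the bound above. On the lower side, UF_Ppr_AF_111419 stood at -0.32 ± 0.29 (SD, n = 5) against 0.64 ± 0.23 (SD, n = 4), with all 5 exposed arrays below all 4 controls, and UF_Ppr_AF_105432 differed by -1.57 (SE 0.44), also without overlap. With normexp these differences were -0.54 and -0.27, and UF_Ppr_AF_105432 was well above background on 2 of 5 exposed arrays. By limma with Benjamini-Hochberg adjustment, 0 of 11492 probes passed and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 281 probes, 85 higher and 196 lower, where 575 would be reached by chance. The count was 145 with normexp, 475 with quantile normalization, 667 without the 3 arrays of doubtful quality and 907 with array weights, so it lay on either side of the chance value. With median scaling, which moved the median difference of all probes by 0.22 log2 units at 24 h, the split was 248 higher and 59 lower, so no direction is given for the set.

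The 24 h count depended on single arrays in a few settings. Without control 24 h replicate 2, UF_Ppr_AF_102490 passed, and without exposed 24 h replicate 1 a different probe, UF_Ppr_AF_106942, passed, 1 in each case. Their log2 differences moved from 2.59 to 3.45 and from -1.79 to -2.59. The smallest adjusted p by limma with Benjamini-Hochberg adjustment ran from 0.0126 to 1 over the alternatives that gave one. The unadjusted count became 430 without exposed 24 h replicate 1 and 449 without exposed 24 h replicate 3. Blocked by slide, 0 probes passed and 267 had an unadjusted p under 0.05. Within slides by limma, 0 passed on slide 1 (2 exposed and 2 control arrays, 174 unadjusted) and on slide 2 (2 and 1, 151 unadjusted). On slide 5, a single exposed array against a single control gave 123 passing probes and 864 unadjusted, with each lone array assumed to vary like the other groups.

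At 48 h, the largest contrast relative to its error was UF_Ppr_AF_100779, which stood at -3.95 ± 1.22 (SD, n = 5) in exposed liver and -1.54 ± 0.40 (SD, n = 5) in controls, a difference of -2.41 (SE 0.47), with all 5 exposed arrays below all 5 controls. With normexp background correction the difference was -1.16. Its adjusted p in limma with Benjamini-Hochberg adjustment was 0.317, so it did not pass. UF_Ppr_AF_101968 differed by -2.42 (SE 0.61), also without overlap, and was well above background on 3 of 5 exposed and 4 of 5 control arrays; with normexp it differed by -0.89. UF_Ppr_AF_114724 stood at 0.85 ± 0.35 (SD, n = 5) against -0.08 ± 0.10 (SD, n = 5), a 1.90-fold difference without overlap. UF_Ppr_AF_103347 was higher by 1.48 log2 units, or 0.70 with normexp, with overlapping arrays. In limma 0 probes passed, and 488 had an unadjusted p under 0.05, 173 higher and 315 lower. This split became 253 and 270 with quantile normalization and 257 and 211 with median scaling. The unadjusted count was 299 with normexp and 769 with array weights.

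The 48 h unadjusted count was 774 without control replicate 1, 304 without control replicate 2 and 848 without exposed replicate 2. A fit with slide as a block gave 0 passing probes in limma, and 510 were below the unadjusted threshold. Within slide 3 and within slide 4, each with 2 exposed and 2 control arrays, 0 passed, with 627 and 431 unadjusted.

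At 72 h, UF_Ppr_AF_104486 was not well above background on any of the 4 exposed arrays and was well above it on 4 of the 5 controls. By the processed signal it was at least 4.34-fold lower in exposed liver. With normexp its log2 difference was -1.07, short of that bound. UF_Ppr_AF_114809 stood at -0.28 ± 0.78 (SD, n = 4) against 1.01 ± 0.39 (SD, n = 5), a difference of -1.29 (SE 0.34). Higher in exposed liver were UF_Ppr_AM_120399, well above background on 4 of 4 exposed and 2 of 5 control arrays, by 2.55 (SE 0.64; 0.59 with normexp), and UF_Ppr_AF_100015, by 2.34 (SE 0.64), both without overlap of the 4 exposed and 5 control arrays. In limma 0 probes passed after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.893. At an unadjusted p under 0.05 there were 605, 236 higher and 369 lower. The unadjusted count was 308 without exposed 72 h replicate 4, 1 of the 2 arrays with raised bright-corner spots, and 923 without exposed 72 h replicate 3. It was 360 without the 3 arrays of doubtful quality and 923 with array weights.

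At 72 h a fit blocked by slide gave 0 passing probes in limma, and 519 had an unadjusted p under 0.05. Within slides, slide 1 (1 exposed and 1 control array) gave 1 passing probe and 334 unadjusted. Slide 2 (1 and 2 arrays) gave 0 and 182, and slide 5 (2 and 2 arrays) gave 0 and 663.

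Averaged over the 3 times, which is the comparison with the smallest error here, UF_Ppr_AF_114579 was higher in exposed liver by 2.46 log2 units (SE 0.60). Its differences were 2.498, 2.41 and 2.49 at 24, 48 and 72 h, and 12 of 14 exposed arrays lay above the control mean of their time. At 72 h it was well above background on 0 of 5 control arrays, so the size of that difference depends on the background correction. It was a dim probe, well above background on 9 exposed and 3 control arrays. UF_Ppr_AF_104856, well above background on 9 exposed and 2 control arrays, differed by 1.89 (SE 0.52), with 13 of 14 exposed arrays above the control mean of their time. None of its 2 bright controls was of 24 h, where it was well above background on 0 of 4. With normexp background correction the averaged differences of these 2 probes were 0.64 and 0.18. Lower were UF_Ppr_AF_100779, by -1.18 (SE 0.28, 12 of 14 exposed arrays), and UF_Ppr_AF_108151, by -1.07 (SE 0.26, 13 of 14), or by -0.49 and -0.46 with normexp. None passed: all 4 had an adjusted p of 0.836 by limma with Benjamini-Hochberg adjustment, and 0 of 11492 probes passed.

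For that average, 551 probes had an unadjusted p under 0.05 in limma, 141 higher and 410 lower, against 338 and 189 with median scaling. The count was 284 without exposed 72 h replicate 4, 835 without exposed 72 h replicate 3 and 862 without exposed 48 h replicate 2. It was 266 with normexp, 298 without the 3 arrays of doubtful quality and 867 with array weights. The 95% confidence interval of the averaged difference lay within 2-fold either way for 62.1% of probes and within 4-fold for 95.6%. At single times the interval lay within 2-fold for 19.2% at 24 h, 20.8% at 48 h and 17.1% at 72 h. Blocked by slide, 0 passed and 515 were below the unadjusted threshold.

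**Figure D2:**
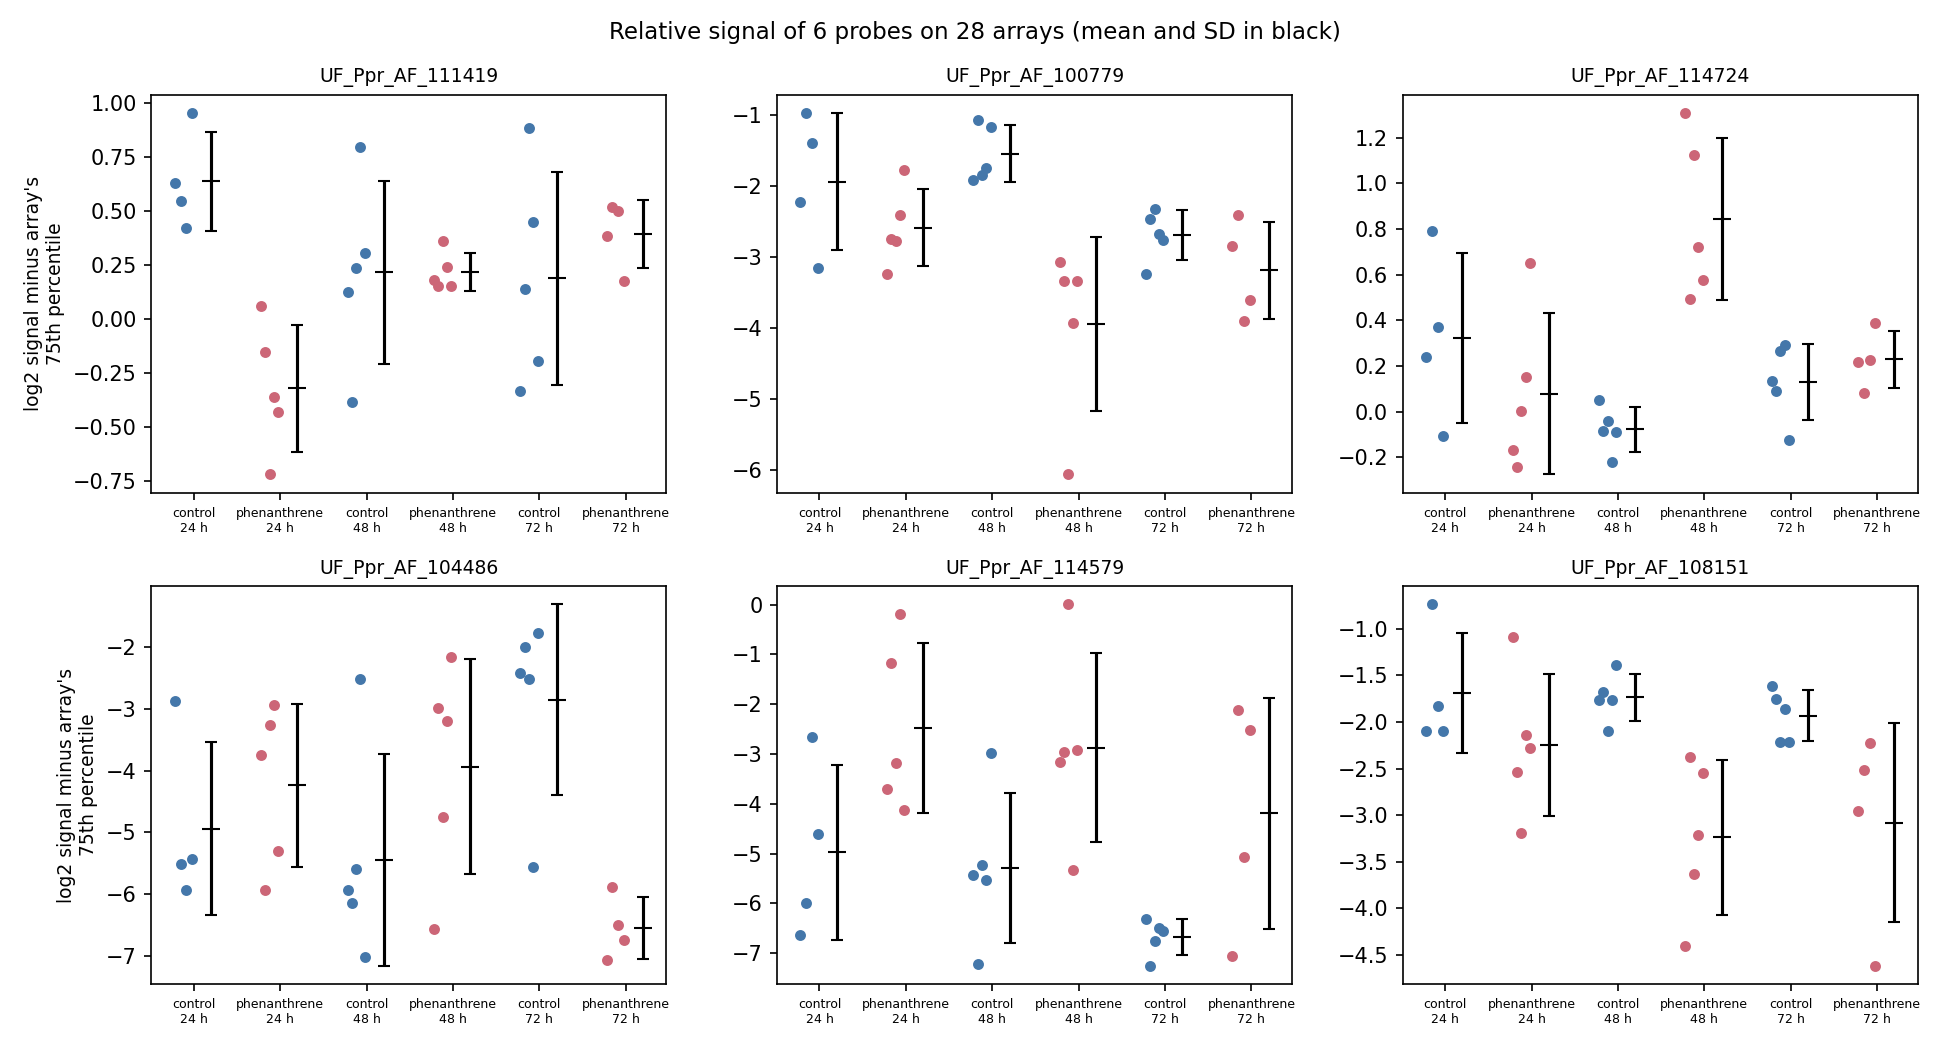
Points are single arrays and black bars are the mean and SD of each group for 6 probes, on a scale of log2 signal minus the 75th percentile of the array. UF_Ppr_AF_100779 has a mean of -3.95 in exposed and -1.54 in control liver at 48 h, while UF_Ppr_AF_114579 has higher exposed means at all 3 times, with overlapping arrays at each time.

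Whether the phenanthrene effect differed between times was tested by an F test in limma, and 0 probes passed, with a smallest adjusted p of 1 by Benjamini-Hochberg adjustment. There were 392 probes at an unadjusted p under 0.05. The probe with the smallest p was UF_Ppr_AF_113861, whose difference was 2.96 at 24 h, -4.99 at 48 h and 0.92 at 72 h. The 48 h difference minus that of 24 h was -7.95, or -3.54 with normexp. Its SD was as high as 3.54 log2 units, in the 24 h controls (n = 4). With array weights, 1 probe passed and 943 were unadjusted. Adding slide as a block left 0 passing in limma, and 374 were below the unadjusted threshold.

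Control liver was compared between times as a background. Between 24 and 48 h, UF_Ppr_AF_112748 was lower at 48 h by -3.30 (SE 0.75) and UF_Ppr_AF_104491 was higher by 1.77 (SE 0.48), and neither passed. In limma 0 probes passed and 598 had an unadjusted p under 0.05, 136 higher and 462 lower at 48 h. The unadjusted count was 208 with normexp, 908 without the 3 arrays of doubtful quality and 1873 with array weights. With array weights, 38 passed, 4 of them higher at 48 h. A fit to only the 9 arrays compared gave 1 passing probe and 1193 unadjusted. Leaving out control 24 h replicate 4 let UF_Ppr_AF_112748 pass and moved its difference from -3.30 to -4.36. Blocked by slide, the counts were 0 passing and 367 unadjusted, or 0 and 656 with slide as a random block, and within slide 2, with 1 array of each time, 0 and 329.

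Between 24 and 72 h in controls, UF_Ppr_AF_115263 was higher at 72 h by 2.22 (SE 0.63) and UF_Ppr_AF_118889 differed by -2.24 (SE 0.56), each without overlap of 5 and 4 arrays. With normexp these differences were 1.31 and -0.55, and UF_Ppr_AF_118889 was well above background on 2 of 5 arrays at 72 h and 3 of 4 at 24 h. In limma 0 probes passed and 473 were below the unadjusted threshold, 97 higher and 376 lower, a split that became 410 and 133 with median scaling. The unadjusted count was 203 with normexp, 752 without the 3 arrays of doubtful quality, 1025 in a fit to the arrays compared and 1656 with array weights. The count was 308 without control 24 h replicate 3 and 279 without control 72 h replicate 3. It was 443 with slide as a block, where 0 passed. Within slide 1 (1 array of 72 h and 2 of 24 h) 3 probes passed, with 271 unadjusted, while 0 passed on slide 2 (245 unadjusted) and on slide 5 (233 unadjusted).

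Between 48 and 72 h in controls, UF_Ppr_AF_102176 was 4.11-fold higher at 72 h and UF_Ppr_AF_117272 was 2.33-fold lower, with n = 5 in each group and overlapping arrays. With normexp the log2 difference of UF_Ppr_AF_117272 was -0.76 in place of -1.22. In limma 0 probes passed and 421 had an unadjusted p under 0.05, 234 higher and 187 lower, a split that became 449 and 115 with median scaling and 373 and 134 with quantile normalization. The unadjusted count was 224 with normexp, 661 without the 3 arrays of doubtful quality, 661 in a fit to the arrays compared and 1162 with array weights. Most 48 h controls were scanned on the first day and all 72 h controls on the second. With slide as a fixed block 1 probe, UF_Ppr_AF_109657, passed and 224 were unadjusted, while with slide as a random block 0 passed in limma and 454 were unadjusted. That probe was bright on 3 of the 28 arrays, 2 control and 1 exposed, all of 48 h, and dim on the others. Its log2 difference was -4.03 without a block and -9.27 with slide as a fixed block. Within slide 2, with 2 arrays of 72 h and 1 of 48 h, 0 passed and 177 were unadjusted.

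**Figure D3:**
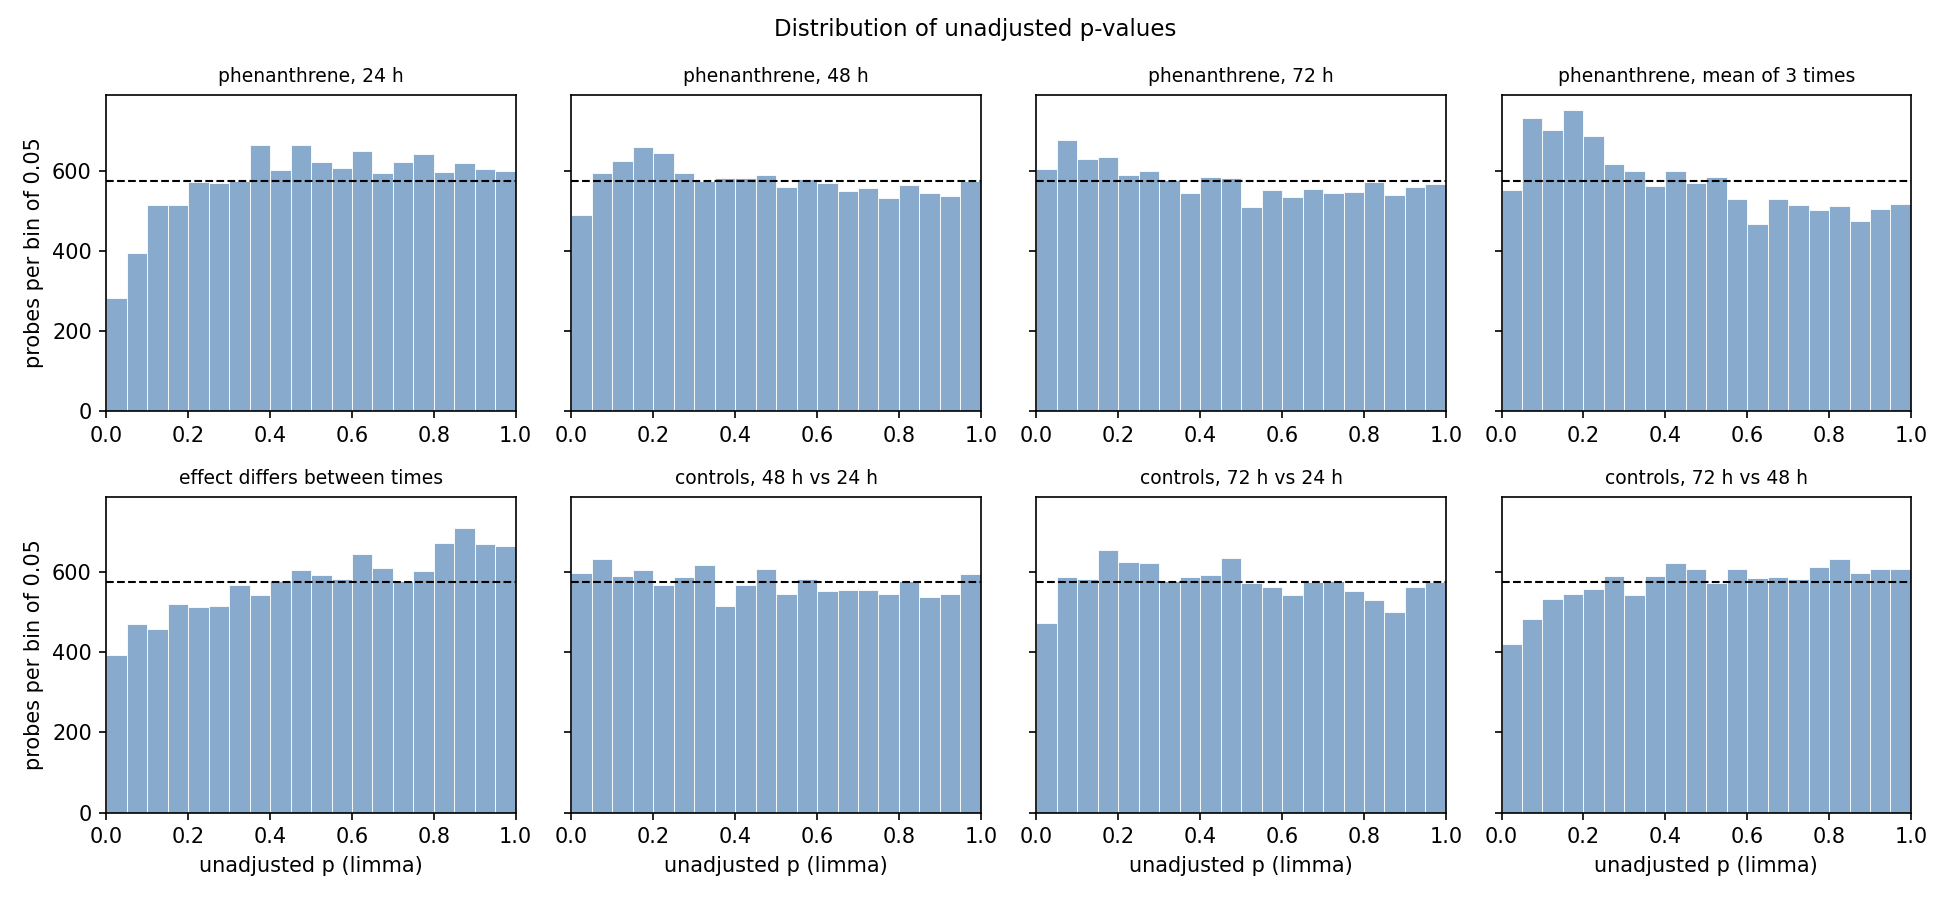
Each panel counts the 11492 tested probes per bin of 0.05 of the unadjusted limma p-value, and the dashed line marks the 575 probes per bin that chance gives. The first bin holds 281, 488 and 605 probes for phenanthrene at 24, 48 and 72 h and 551 for the mean of the 3 times.

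Groups without overlap were about as frequent as chance gives for phenanthrene. Exposed and control arrays did not overlap at 144 probes at 24 h, 78 at 48 h and 186 at 72 h, or 1.32%, 0.71% and 1.70% of 10933, where chance gives 1.59%, 0.79% and 1.59%. In controls, 464 probes (4.24%) did not overlap between 24 and 48 h, where chance gives 1.59%, and 2 of all 126 splits of those 9 arrays, the real one included, gave as many. Between 24 and 72 h the number was 405 (3.70%, chance 1.59%), reached in 6 of 126 splits. Between 48 and 72 h it was 84 (0.77%, chance 0.79%). Time and scan day overlapped in the comparisons of 24 with 48 h and of 48 with 72 h, while all control arrays of 24 and 72 h were scanned on the second day.

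Whole profiles of exposed and control arrays were not separated beyond chance at any of the 3 times. The mean correlation over 10933 probes was 0.906 between agents and 0.901 within agents at 24 h, 0.896 and 0.895 at 48 h, and 0.901 and 0.903 at 72 h. One-sided exact permutation tests of the separation gave p = 0.778, 0.492 and 0.397, with Benjamini-Hochberg adjusted values of 0.778, 0.738 and 0.738 over the 3 tests. The log2 differences at 24 and 48 h correlated across 11492 probes with r = 0.11 (rho = 0.08), those at 24 and 72 h with r = 0.06 (rho = 0.06), and those at 48 and 72 h with r = 0.13 (rho = 0.17). Probes are not independent replicates. Of 100 relabelings of the arrays within each time, the real one included, 29, 26 and 34 gave an r as high.

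The size of change that 28 arrays could show was measured in simulated data with 200 changed probes among 10933. Each draw mixed 50 probes at each of 2-, 4-, 8- and 16-fold. Strong changes ease the Benjamini-Hochberg cutoff for weak ones, so the shares hold for this mix only. Changes were added in full on the log2 scale to probes picked at random, so the shrinking of differences near background was not simulated. The shares may therefore be too high for dim probes. Residuals of the arrays of doubtful quality could fall in any group, while in the data those arrays were all exposed ones. For phenanthrene at 24 h, 5.2% of 2-fold, 43.1% of 4-fold, 76.7% of 8-fold and 90.9% of 16-fold changes were recovered by limma. The shares were 9.3%, 54.3%, 79.9% and 92.6% at 48 h and 6.4%, 46.5%, 77.2% and 91.7% at 72 h. For the mean of the 3 times they were 40.1%, 89.2%, 97.6% and 99.1%. For an effect present at only 1 time, the test of a difference between times recovered 0.7%, 22.4%, 51.6% and 73.1%.

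**Figure D4:**
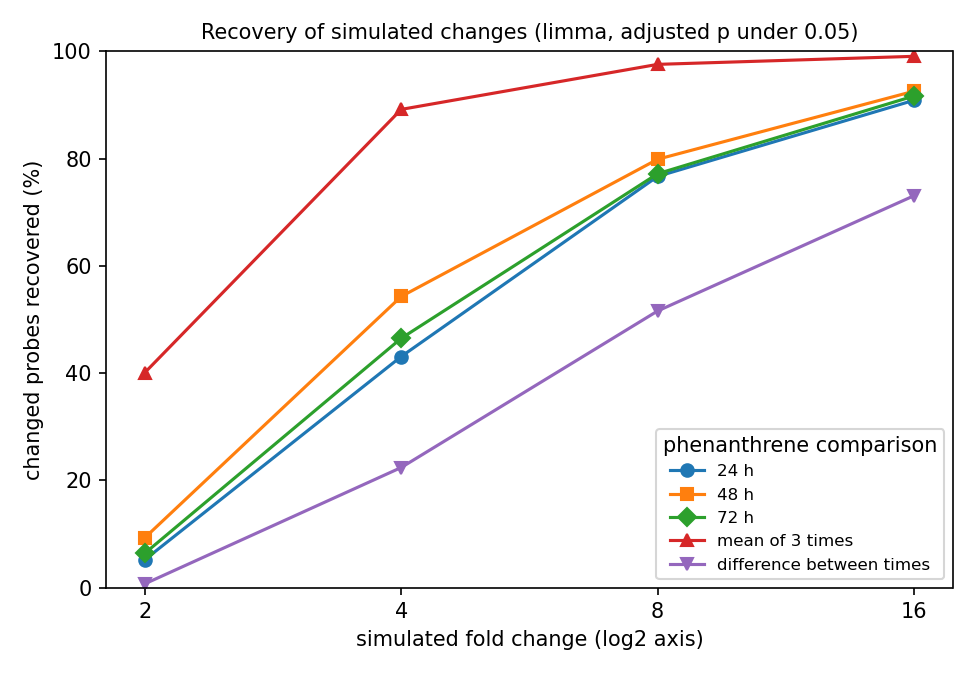
The percentage of simulated changed probes recovered at an adjusted p under 0.05 is plotted against the simulated fold change on a log2 axis, with 1 line for each phenanthrene comparison. Each draw held 50 changed probes at each fold. For 4-fold changes the mean of the 3 times reaches 89.2% and the single times 43.1%, 54.3% and 46.5%.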

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

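The tests of overall brightness and of slide for the pair of arrays with raised bright-corner spots were chosen after the result was seen, and the slide and single-probe tests gained a requirement on their spread after their values were seen. Of 30 group tests on array measures and 64 on the probes named, 10 and 6 marked an array whose gap to its group exceeded the 95% critical value of Dixon, where chance marks about 1 in 20 groups.

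The bright-corner spots of exposed 48 h replicate 1 lay at 17.87 log2 units, with the rest of its group at 10.32 to 11.21, and those of exposed 72 h replicate 4 at 19.004, with the rest at 10.88 to 11.13. Both also lay above the 14 control arrays, which reached 11.85. These 2 arrays had 201 and 498 non-uniform spots, against at most 5 and 12 in the rest of their groups. Exposed 72 h replicate 4 also had 8865 probes well above background, against 10827 to 11202, and the lowest mean correlation with its group, 0.839 against 0.898 to 0.906.

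The probe deviations of these 2 arrays from their groups correlated at 0.44 over 10933 probes, and 3 of 325 other array pairs had an r as high (range of the others -0.67 to 0.55). Exposed 72 h replicate 4 was the brightest array, with a 75th percentile of 1253 against 214 to 343 in its group and 36 saturated spots, but brighter labelling or scanning of the whole array is argued against as the shared cause: that of exposed 48 h replicate 1, 334, lay within the 220 to 511 of its group, the 10 spike-in probes shifted by a median of 0.64 and 0.61 log2 units, at least 6.22 less than the bright-corner spots by which the arrays were picked, and the correlation was 0.40 after quantile normalization, which removes a monotone distortion. The slide is argued against too, since the other arrays of each slide had a median correlation with them of -0.018 (SE 0.015, 3 arrays) and -0.041 (SE 0.043, 6 arrays). Noise of single probes stays open, since the mean deviation of the 2 arrays correlated at only 0.16 between 2 probes of the same contig (230 contigs, up to 0.21 with shuffled partners). Array quality was not tested as the shared cause and stays open: these 2 arrays alone held saturated spots, 8 and 36. They also had the most non-uniform spots. A shared state of these samples could be another candidate explanation but was not tested, because the labels describe no such state.

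Exposed 24 h replicate 3 had 5127 probes well above background, while its group otherwise had 9216 to 10409. Control 24 h replicate 4 had 13 non-uniform spots against 0 to 2, and control 48 h replicate 4 had 7 against 0 to 2. The bright-corner signal of control 24 h replicate 2 was 10.75, below the 11.38 to 11.48 of its group.

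Among the named probes, UF_Ppr_AF_100779 was at -6.07 on exposed 48 h replicate 3, below the -3.92 to -3.07 of its group. UF_Ppr_AF_104486 was at -5.56 on control 72 h replicate 4, against -2.51 to -1.77. UF_Ppr_AF_114809 was at 0.33 on control 72 h replicate 5, against 1.06 to 1.29. UF_Ppr_AF_112748 was at -0.95 on control 24 h replicate 4, against 2.80 to 3.54. UF_Ppr_AF_118889 was at -7.13 on control 72 h replicate 3, against -5.69 to -5.28. UF_Ppr_AF_113861 was at -0.70 on control 48 h replicate 5, against 0.66 to 0.97.

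Other splits of the same arrays gave as many probes at an unadjusted p under 0.05 as the real grouping, and by this count chance could not be excluded for any of the 8 comparisons. Each comparison had 100 splits, the real one included and the others drawn at random. Of these, 87 reached the 281 probes of 24 h (highest other 837), 58 the 488 of 48 h (1822), 33 the 605 of 72 h (1482) and 42 the 551 of the averaged effect (1815). For the difference between times 62 reached 392 (1746). In controls, 5 of 100 reached the 598 of 24 to 48 h (812), 8 the 473 of 24 to 72 h (674) and 26 the 421 of 48 to 72 h (875). The 5 of 100 stood exactly at the limit set beforehand, from a draw that did not hold all 126 splits. The count of probes without overlap, chosen after seeing the data, differed for controls: 2 of all 126 splits, the real one included, reached the 464 of 24 to 48 h (highest other 607) and 6 of 126 the 405 of 24 to 72 h (603), without adjustment for the 6 comparisons counted. For phenanthrene the highest splits held several times the real count at 24 and 48 h and for the average and the difference between times, and 1482 against 605 at 72 h, which may point to a structure of the samples other than agent, although no chance value for such a maximum was computed and correlated probes could give one. At 24 h the highest split set all 4 arrays of slide 1 with 1 of slide 2 against the rest, and the real count with slide as a block was 267. The highest splits at 48 and 72 h also mixed slides, and at 48 h 3 of the 4 arrays of slide 4 lay on 1 side and 3 of the 4 of slide 3 on the other. The real counts with slide as a block were 510 and 519, and the consensus correlation within slides was -0.031. Both splits divided the arrays by the first principal component: 8.61 to 87.2 against -38.9 to -4.77 at 48 h, and -8.36 to 147 against -36.8 to -12.3 at 72 h. The upper sides held exposed 48 h replicate 1 and exposed 72 h replicate 4, of doubtful quality. Component and splits come from the same signals, and what the component stands for was not tested.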

How the results depend on the processing

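The alternatives chosen after seeing the data were leaving out the 3 arrays of doubtful quality together (exposed 24 h replicate 3, 48 h replicate 1 and 72 h replicate 4), keeping non-uniform spots, and scan day as a block. Of 355 recomputed counts of passing probes by limma over the 8 comparisons, 344 were 0 as reported. Leaving out single arrays gave 0 to 1 at 24 h and 0 to 1 for controls between 24 and 48 h, and 0 otherwise. Array weights gave 38 for controls between 24 and 48 h and 1 for the difference between times. Slide as a fixed block and scan day as a block each gave 1 for controls between 48 and 72 h and slide as a random block 0, while a fit to the arrays of the 2 groups gave 1 for controls between 24 and 48 h. Within slides, a single exposed array against a single control gave 123 on slide 5 at 24 h and 1 on slide 1 at 72 h, and slide 1 gave 3 for controls between 24 and 72 h. The cause was not tested in these cases. The exposed array of slide 5 at 24 h, replicate 5, had the lowest spike-in shift of all arrays, -1.84 log2 units, and a mean correlation of 0.850 with its group. Exposed 24 h replicate 2 had nearly the same shift, -1.82, and lay on slide 1, where 0 passed at 24 h. Without the 3 doubtful arrays 0 passed in all 8 comparisons, with 667, 509, 360, 298 and 546 probes at an unadjusted p under 0.05 for 24, 48 and 72 h, their mean and their difference, and 908, 752 and 661 in controls.

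Of the unadjusted counts, 286 stayed within 1.5 times the reported one and 48 did not. The counts were not scaled to the number of probes tested, and the filter that left 4710 probes is among the 48 in every comparison. With array weights the unadjusted counts were 769 to 1873. The 23 log2 differences of named probes kept their sign in all 713 recomputed values (quantile, normexp, slide block, single arrays left out), and 2 of these passed. The probes were picked by the smallest p in these same data, so a change of sign was unlikely from the start. Median scaling and array weights were not tried for them. The 3 correlations between times moved by less than the SD over relabelings under all 3 settings tried. No paired analysis was possible because replicate numbers follow the order of deposit. The tests of gene lists and of other probes of a named gene were not run, since no probe has a gene name. Signal over background limits the probes tested: 4710 were well above it on all 28 arrays, and 0 of those passed in any comparison, with 77 to 285 at an unadjusted p under 0.05. The chance value for 4710 probes is lower than the 575 for all 11492. Exposed 24 h replicate 3, with only 5127 probes well above background, limits the 4710.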

Other observations

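The comparison of probe pairs below was chosen after the result was seen. For the second principal component, the tests of brightness and of single-probe noise gained a requirement on their spread after their values were seen, and under the bound first written, an absolute r under 0.2, brightness would have been argued against. The tests of phenanthrene here and of agent, time and array quality below also met the bounds first written, and are left open for the reasons given with them. The second principal component held 15.4% of the variance over 10933 probes and separated arrays within groups, from -106 on exposed 48 h replicate 3 to 117 on exposed 72 h replicate 4. The latter is 1 of the 3 arrays of doubtful quality, and the next highest value was 47.8, on exposed 24 h replicate 5. Exposed 72 h replicate 4 was also highest on the first component, at 147 (18.5% of the variance). Brightness was not tested for that component. The brightest arrays, with 75th percentiles of 1253, 614, 511 and 487, stood at 147, 58.8, 80.6 and 18.3 on it, above its median of -15.1. Exposed 48 h replicate 1, with 334, stood at 87.2. Array quality was not tested for the second component and stays open. Noise of single probes is argued against, since loadings correlated at 0.35 between 2 probes of 1 contig and reached at most 0.30 with shuffled partners. Phenanthrene stays open: exposed and control means differed by 0.018 SDs (permutation p = 0.964, two-sided), but both ends of the component were exposed arrays, which cancel in a mean. Array brightness is left open because the SE of r over 28 arrays is about as large as that bound: the correlation with the 75th percentile was r = 0.038 (permutation p = 0.845; rho = -0.15, p = 0.437) over 28 arrays, and -0.37 (permutation p = 0.061) without the 2 most extreme arrays, with -0.34 and 0.15 on the 2 scan days. Slide stays open too, holding 24.5% of the variance of the component (permutation p = 0.150), so a physiological difference between samples may be proposed only as a hypothesis.

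At some probes arrays of the same group were bright or dim, and a gap of at least 3 log2 units, with at least 3 arrays on each side and every array of the upper side well above background, was present at 17 of 10933 probes. Of these, UF_Ppr_AF_109272 averaged 3.41 on 22 arrays and -5.97 on the other 6, and UF_Ppr_AF_119004 averaged -0.03 on 12 arrays and -6.89 on the others, both named after their values were seen. Agent and time stay open: 0% of the 17 had an unadjusted p under 0.05 in Fisher's exact test for either (smallest adjusted p 1 and 0.498), but only 10 could have reached it for agent and 13 for time, and at 3 of the 4 probes with 3 arrays on the smaller side those arrays were all of 48 h. Without the 3 doubtful arrays 100% still met the definition, so these arrays alone did not make the pattern. Array quality otherwise stays open. The definition asks for only 3 arrays on each side, so probes with many arrays on both sides could hardly fail it. Sequence variation between samples under a probe could be a candidate explanation, against loss of the whole transcript, but 0 of the 17 had a second tested probe of the same contig to tell these apart.

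The bright and dim calls of UF_Ppr_AF_109272 and UF_Ppr_AF_103241 went together. Both were bright on 22 arrays and both dim on 4, and 2 arrays were bright for the second alone. Fisher's exact test gave p = 0.000733 for this pair, or 0.0996 after Benjamini-Hochberg adjustment over the 136 pairs, so it did not pass. UF_Ppr_AF_113872, whose contig shares its number with that of UF_Ppr_AF_109272, ran the other way: both were bright on 6 arrays, 1 alone on 16 and 5, and neither on 1 (Fisher's exact p = 0.0221). Against UF_Ppr_AF_103241 its exact p was 0.0161, and neither passed, with an adjusted p of 0.548 by Benjamini-Hochberg for both.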
